A study of Mus musculus with 6 samples.

How the data were processed

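SMART-seq libraries of wild-type mouse Treg from spleen and lymph nodes were analysed: 2 unstimulated, 2 stimulated and 2 stimulated with iBP, each a separate column of a single table. The design text also names Treg from Kdm2b conditional knockout mice, which were not analysed here. Per the labels, cells were lysed in TRIzol, RNA was primed with oligo-dT and cDNA was amplified by PCR. The authors deposited FPKM values, which are read fragments scaled to transcript length and to the number of mapped fragments, with no further scaling between libraries stated. The submitters' processing notes name HISAT2 2.2.1 for alignment, StringTie 2.1.1 for quantification and the mm10 assembly. The annotation, the filters, the treatment of multi-mapped reads and the strand of the libraries are not given in the sources used here, so genes that overlap or have close copies may share reads. FPKM fixes each library's total only roughly, so a large change in a few abundant genes would move all others. Read depth is unknown, and PCR copies were not separated by molecular identifiers.

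Values were analysed as log2(FPKM + 1). Genes with FPKM of at least 1 in at least 2 libraries were tested, 10436 of 24421. A linear model with the 3 groups was fitted to all 6 libraries with limma 3.58.1 in R 4.3.3, with moderated variances and a trend with mean level (3 residual and 8.52 prior degrees of freedom). Tests were two-sided, with Benjamini-Hochberg adjustment over the tested genes and an adjusted p under 0.05 taken as passing. Errors of log2 differences are standard errors from that fit, and errors of group means are standard deviations of 2 libraries. The labels do not say whether the 2 libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. They do not say either that equal replicate numbers mark a shared animal or day, so the replicate number is not a term of the model. When a library is left out, its group has 1 library, which is assumed to vary like the other groups.

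Gene lists, 40 in number, the comparisons, the tests and the rule for named genes were fixed before the data were examined. A list was tested with camera (limma) at a preset correlation of 0.01 when at least 3 of its genes were tested, which left 37, with Benjamini-Hochberg adjustment over the lists. Camera sets a list against all other tested genes. It was repeated with an estimated correlation, and fry was run, which tests whether a list's genes move on balance in 1 direction without comparing them with other genes, and in its mixed form whether they change in either direction. Named genes in stimulated against unstimulated and in iBP against stimulated are the 12 largest fitted rises and the 12 largest falls among genes that passed, had no overlap between libraries and a mean FPKM of at least 5 in the higher group. For iBP against unstimulated 5 each way were taken. Predicted genes, clones and pseudogenes were left out. Where fewer passed, genes with the smallest unadjusted p were added, up to 5 each way. Up to 5 members of each list with the largest differences are named, and a fixed set of Treg and Polycomb genes is always given. Some genes that come under this rule are not reported.

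To ask whether genes of the response to stimulation differed with iBP, they were chosen by the mean of both stimulated groups against unstimulated. The errors of that contrast are independent of those of iBP against stimulated in a balanced design. The iBP difference of the chosen genes was tested with camera and fry. No group was given iBP without stimulation, so an altered response cannot be told apart from an effect of iBP alone. Covariances of changes across genes were set beside 100 simulations with no effect. Coordinates come from GENCODE M21 for GRCm38, matched by gene symbol. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

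The test was run on simulated data with the design of stimulated against unstimulated, 10436 genes, 20 runs and 200 changed genes per run. It recovered 12.1% of changes of 0.5 (log2), 53.3% of changes of 1 and 97.1% of changes of 2, and 7.5% of its calls were unchanged genes. A comparison with no change gave 1.3 calls on average and 6 at most, with at least 1 call in 12 of 20 runs. Both the 7.5% and the 12 of 20 runs are above what an adjusted p under 0.05 should allow. Adjusted p-values of genes in the report may thus be too small, and calls near 0.05 are the least secure. A list of 20 genes raised by 0.5 had an unadjusted camera p under 0.05 in 100% of runs and an unchanged list in 10%. The lists of the report were instead judged by an adjusted p. Genes were simulated independently, so this check does not cover correlation between the genes of a list.

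Alternatives were a pseudocount of 0.1, no filter on low values, a minimum FPKM of 5, rescaling to TPM, median-of-ratios scaling, quantile normalization, no variance trend, robust variance moderation, a replicate term, only the 2 groups compared, leaving out each library, a 2-fold minimum and an adjusted p under 0.1. An alternative without microRNA and small nucleolar RNA genes was chosen after seeing the data.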

Results

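Polyadenylated RNA from wild-type mouse regulatory T cells (Treg), the Foxp3-expressing CD4 lymphocytes that restrain immune responses, was profiled by SMART-seq, a method that copies poly(A) RNA into full-length cDNA and amplifies it by PCR. The cells came from spleen and lymph nodes and formed 3 groups of 2 libraries: unstimulated, stimulated, and stimulated in the presence of iBP. The study's design describes iBP as inhibition of H2AK119ub1, the monoubiquitin mark that Polycomb repressive complex 1 (PRC1) places on lysine 119 of histone H2A. The kind of stimulus, its duration and the dose of iBP are not given in the labels. Expression was given as FPKM for 24421 genes. Summed FPKM was 381302 and 374088 in the unstimulated libraries, 375821 and 378906 in the stimulated ones, and 366044 and 366722 with iBP. Between 12596 and 13592 genes per library had a value above 0. Read depth per library is unknown, so no counting error can be attached to a single value, and the precision of each difference comes from the spread between libraries.

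The first comparison, stimulated against unstimulated, asks which genes differ in these Treg preparations after stimulation. Among the genes that rose were Il22, Csf2, Socs1, Cish, Gpr83 and Foxp3, and among those that fell Bcl6 and Tcf7. Il22, which encodes interleukin 22, a cytokine that acts on epithelium, went from a mean FPKM of 1.92 ± 0.0979 to 157 ± 38.5 (SD, n = 2 libraries per group), a rise of 5.73 ± 0.22 (log2, SE; adjusted p = 1.56e-07). Socs1, a feedback inhibitor of JAK/STAT signalling, read 44.7 and 43.3 FPKM in unstimulated and 317 and 288 in stimulated libraries, a rise of 2.75 ± 0.12 (adjusted p = 2.03e-07). Foxp3, the transcription factor that defines the lineage, went from 41.3 ± 8.20 to 111 ± 14.3, a rise of 1.41 ± 0.16 (adjusted p = 0.000923). In all, 135 of 10436 tested genes passed the limma test, 101 higher and 34 lower, and 72 of them differed at least 2-fold.

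Cytokine genes took 4 of the 12 named rises. Beside Il22 these were Csf2, which encodes GM-CSF (log2 2.64 ± 0.29, adjusted p = 0.000854), Il17a (2.45 ± 0.31, adjusted p = 0.00184) and Lta, which encodes lymphotoxin alpha (1.72 ± 0.15, adjusted p = 0.000125). Csf2 read 8.35 and 3.78 FPKM without stimulation and 36.6 and 45.2 with it, and Il17a read 1.36 and 0.643 against 10.6 and 8.98. Gpr83, a G protein-coupled receptor gene characteristic of Treg, rose by 2.32 ± 0.12 (adjusted p = 1.92e-06) and read 31.6 and 31.8 FPKM against 162 and 163. Gpr146, another receptor gene, rose by 2.05 ± 0.24 (adjusted p = 0.00129), and Cish, a feedback inhibitor induced by STAT5, by 1.84 ± 0.14 (adjusted p = 4.85e-05). Gzmb, the granzyme B gene, rose by 1.86 ± 0.28 (adjusted p = 0.00559) and Mfsd2a, a lysophospholipid transporter gene, by 1.74 ± 0.27 (adjusted p = 0.00632). The list also held a pair of microRNA genes that lie inside rising genes on the same strand, so that their reads cannot be separated from those of the host. These were Mir704 (2.86 ± 0.50, adjusted p = 0.0166) within Pdia4, which itself rose by 1.19 (adjusted p = 0.000923), and Mir6974 (2.47 ± 0.33, adjusted p = 0.0025) within Lta. Mir704 read 7.9e-05 FPKM in unstimulated replicate 1. Among these 12 genes, the call ended for Gzmb without stimulated replicate 2 (adjusted p = 0.111) and for Mfsd2a without stimulated replicate 1 (0.0747). For Mir704 it ended without stimulated replicate 1 (0.0687), stimulated replicate 2 (0.188) or unstimulated replicate 1 (0.0512).

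The largest named fall was in Dnajb11, a co-chaperone of the endoplasmic reticulum, from 19.0 ± 2.87 to 2.57 ± 0.172 FPKM, a log2 difference of −2.48 ± 0.23 (adjusted p = 0.000198). Bcl6, a transcriptional repressor that drives follicular T-cell programmes, read 72.0 and 64.7 FPKM without stimulation and 13.3 and 15.4 with it (−2.18 ± 0.17, adjusted p = 6.71e-05). Tcf7, which encodes the naive and memory T-cell factor TCF1, fell by 0.95 ± 0.14 (adjusted p = 0.00559), and the phosphatase gene Dusp10 fell by 1.06 (adjusted p = 0.000923). Sdcbp2 fell by 0.86 (adjusted p = 0.00498). The calls of the other named falls depended on single libraries. Rpl26, a ribosomal protein gene with many processed pseudogenes, differed by −2.16 ± 0.39 (adjusted p = 0.0192), and its call ended without stimulated replicate 1 (0.135), stimulated replicate 2 (0.061), unstimulated replicate 1 (0.105) or unstimulated replicate 2 (0.0695). Rnf187 (−1.32, adjusted p = 0.0052) lost its call without stimulated replicate 2 (0.0652), and Ccdc117 (−1.23, 0.0115) without stimulated replicate 2 (0.126) or unstimulated replicate 1 (0.0691). Tubb2a (−1.07, 0.0244) lost it without stimulated replicate 2 (0.231), unstimulated replicate 1 (0.0976) or unstimulated replicate 2 (0.0845), and Gramd3 (−0.89, 0.0115) without stimulated replicate 1 (0.0799) or unstimulated replicate 1 (0.0913). Cactin (−1.05, 0.0401) and Armc7 (−0.87, 0.0462) lost theirs without any 1 of the 6 libraries, with adjusted p up to 0.251 and 0.22.

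Of 37 gene lists tested against the other genes with camera at a preset correlation of 0.01, 5 rose with stimulation and 0 fell. In the IL-2/STAT5 response list, 10 of 20 genes rose and 0 fell over all genes tested, and 11 rose adjusted over the list alone (median log2 0.74, adjusted p = 4.78e-09; adjusted p = 0.152 with an estimated correlation). Its members Socs1 and Cish are given above; Bcl2, a survival gene, rose by 1.61 (adjusted p = 0.000668), and Lif, a cytokine gene, by 1.70 (adjusted p = 0.0151). The Lif call ended without stimulated replicate 1 (0.106) or 2 (0.128). In the effector cytokine list, 4 of 20 genes rose (10 rose and 1 fell adjusted over the list alone; median 0.63, adjusted p = 1.08e-07; adjusted p = 0.152 with an estimated correlation). Its member Il17f, at 1.92, did not pass the test over all genes (adjusted p = 0.0839) but passed without stimulated replicate 1 (0.029). In the Treg core list, 11 of 25 genes rose and 0 fell (13 rose adjusted over the list alone; median 0.43, adjusted p = 9.14e-07; adjusted p = 0.246 with an estimated correlation). Beside Gpr83 and Foxp3 these included Ecm1 (1.66, adjusted p = 3.06e-05), an extracellular matrix protein gene, Entpd1 (1.59, adjusted p = 0.00632), which encodes the ectonucleotidase CD39, and Il2ra (0.92, adjusted p = 0.00364), the IL-2 receptor alpha chain. Entpd1 lost its call without stimulated replicate 1 (0.0776). Other Treg genes did not pass: Ctla4 at 0.42 (adjusted p = 0.114), Ikzf2 at −0.19 (0.746) and Il10 at −0.24 (0.601).

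Ribosome biogenesis genes, which build ribosomal RNA and assemble subunits, rose as a list although 0 of 41 members passed over all genes (1 adjusted over the list alone, Nop2 at 0.74, which passed over all genes without unstimulated replicate 2, at an adjusted p of 0.0124). Their median was 0.30 and 37 of 41 differences were positive (adjusted p = 9.21e-08; adjusted p = 0.262 with an estimated correlation). The interferon response list had a smaller shift: 0 of 36 members passed over all genes and 2 rose adjusted over the list alone, with a median of 0.15 (adjusted p = 0.0425; adjusted p = 0.594 with an estimated correlation). Its largest differences were Gbp5 at 1.09 (adjusted p = 0.0782) and Oasl2 at −0.89 (0.298). That call ended without unstimulated replicate 2 (adjusted p = 0.365), stimulated replicate 1 (0.113), stimulated replicate 2 (0.113), iBP replicate 1 (0.0687) or iBP replicate 2 (0.0665), and also after rescaling to TPM (0.197), without the filter on low values (0.077) and with only the 2 groups in the fit (0.0662). With fry, which asks whether a set moves on balance in 1 direction, 6 lists passed, all higher; with an estimated correlation in camera, 0 did. With fry for change in either direction, 24 did. The estimated correlation was 0.0135 for the IL-2/STAT5 list and −0.0144 for effector cytokines, near or below the preset value. Their unadjusted camera p still went from 1.29e-10 to 0.00823 and from 8.72e-09 to 0.00815. The larger p-values of that form thus do not by themselves show strong correlation within a list.

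Lists of T-cell state held genes that moved both ways. Among resting and naive T-cell genes, 1 of 25 rose (Bcl2) and 3 fell (1 and 4 adjusted over the list alone; adjusted p of the list 0.0802, but lower at 0.0271 without unstimulated replicate 1, 0.0454 with a minimum FPKM of 5 and 0.0192 without the filter). Beside Tcf7 the falls were Cd27 (−0.70, adjusted p = 0.0264) and the lymph-node homing receptor gene Ccr7 (−0.50, 0.0344). Without stimulated replicate 2 these calls ended, at 0.185 and 0.148. They also ended without unstimulated replicate 1 (0.132 and 0.0998), for Cd27 without stimulated replicate 1 (0.0818), and for Ccr7 without unstimulated replicate 2 (0.0932), iBP replicate 1 (0.0983) or iBP replicate 2 (0.104). Immediate-early T-cell receptor genes had 2 rises among 25, Jun (1.02) and Myc (0.95), against 4 rises and 2 falls adjusted over the list alone (list adjusted p = 0.398). Cd69, an early activation marker in that list, differed by 0.17 (adjusted p = 0.653). Helper lineage regulators had 1 rise, Irf4 (0.81, adjusted p = 0.00918), and 1 fall, Bcl6, of 23 (the same counts adjusted over the list alone; list adjusted p = 0.938). The Irf4 call ended without stimulated replicate 2 (0.0867) or unstimulated replicate 1 (0.0554).

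Proliferation, metabolism and stress lists did not pass the test. Of 52 cell cycle genes 0 passed, over all genes or adjusted over the list alone (list adjusted p = 0.779). Glycolysis had 1 rise of 20, Hif1a at 0.90 (2 rises and 1 fall adjusted over the list alone; 0.114), and the glucose transporter gene Slc2a1 stood at 0.68 (adjusted p = 0.0501). The lists of oxidative phosphorylation (0.734), cholesterol synthesis (0.938), fatty acid synthesis (0.734), amino acid transport and ATF4 targets (0.152), heat shock (0.734) and MHC class I (0.491) had 0 members past the test over all genes. Adjusted over the list alone, cholesterol synthesis and fatty acid synthesis had 1 rise each and the others 0. The unfolded protein response list had 1 rise, Pdia4, and 1 fall, Dnajb11, of 23 (0.366). Oxidative stress had 1 rise and 1 fall of 15 (0.734), the p53 response 1 rise of 20, Fas at 1.01 (0.491), and cytotoxicity 1 rise of 14, Gzmb (0.273). Adjusted over the list alone, the p53 response had 1 rise and 2 falls and cytotoxicity 2 rises, and the unfolded protein response and oxidative stress lists kept their counts. Fas lost its call without stimulated replicate 2 (adjusted p = 0.0547). Ribosomal protein genes had 1 fall of 36, Rpl26, and the same adjusted over the list alone (0.779); the list passed in opposite directions without stimulated replicate 1 (lower, 0.00199) and without stimulated replicate 2 (higher, 0.012). With fry for change in either direction several of these lists passed: the unfolded protein response (adjusted p = 0.00101), cytotoxicity (0.00128), amino acid transport (0.00229), the p53 response (0.00229), glycolysis (0.00662), fatty acid synthesis (0.0136), heat shock (0.0145), cell cycle (0.0419) and cholesterol synthesis (0.0442). Median and mean differed in sign for cell cycle (0.02 and −0.02), fatty acid synthesis (−0.06 and 0.12) and helper lineage regulators (0.11 and −0.03).

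**Figure D1:**
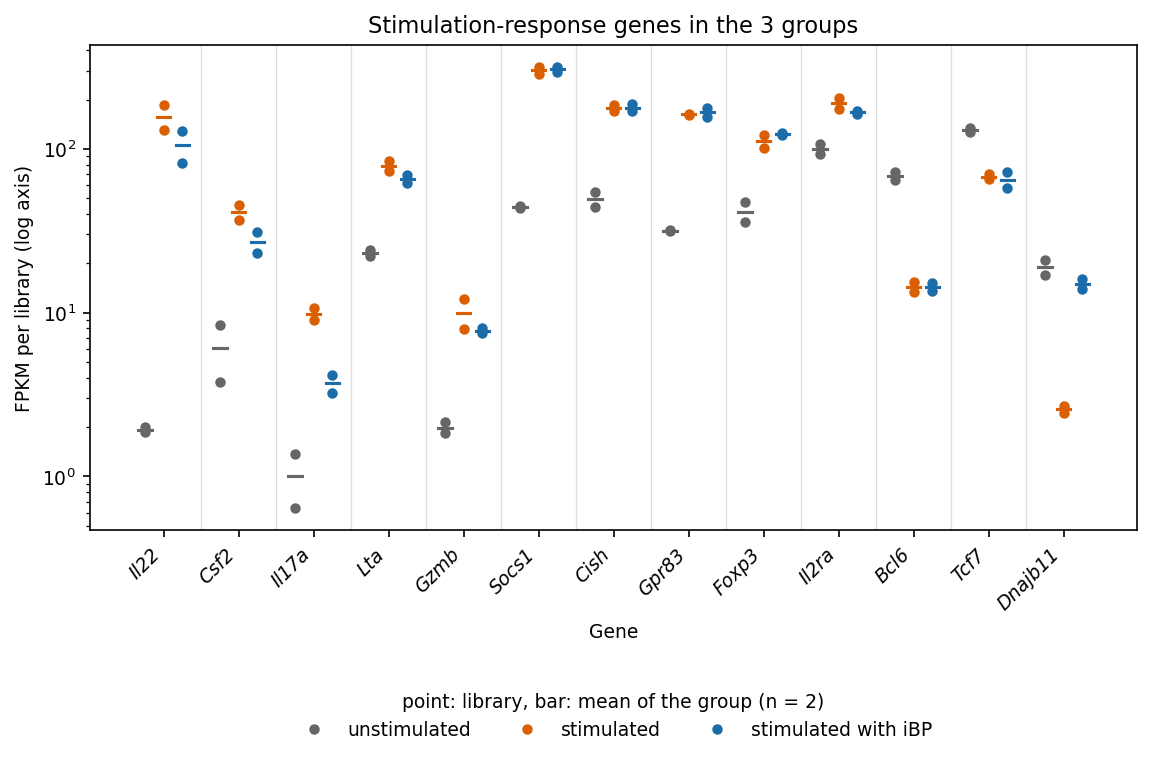
FPKM on a log axis for 13 genes in each library, by group, with points for libraries and bars for group means (n = 2). Il22 stands at 1.85 and 1.99 unstimulated and at 82.5 or more in the other 4 libraries, whereas Dnajb11 is low only in the stimulated libraries without iBP, at 2.69 and 2.44.

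The number of genes past the test moved with single libraries: 54 without stimulated replicate 2, 81 without stimulated replicate 1 and 84 without unstimulated replicate 1. It was 12 without the filter on low values and 12 without the variance trend. Unstimulated replicate 1 stood apart from the rest, at −37.9 on the first principal component against −9.32 for unstimulated replicate 2 and 10.5 to 13.3 for the other 4 libraries. The Pearson correlation across genes was 0.967, 0.974 and 0.975 within the groups and 0.957 to 0.976 between them, where genes are not independent replicates.

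Markers of other cell types were present in all groups. The purity of the cells is not given in the labels, and a difference between groups may come in part from cells other than Treg. B-cell markers took 2.51% of summed FPKM in unstimulated, 2.51% in stimulated and 2.50% in iBP libraries (SD 0.293, 0.166 and 0.0305, n = 2). Cd79a, a B-cell receptor component, read 280 and 276, 291 and 234, and 265 and 283 FPKM in the 3 groups, and H2-Aa, an MHC class II gene, read 2231 and 2255, 2276 and 2250, and 2216 and 2328. Cd3e, a T-cell receptor component, read 57.6 and 67.2, 67.3 and 69.0, and 68.6 and 83.3. Dendritic-cell markers, which include MHC class II, took 1.29%, 1.27% and 1.33%, and myeloid markers 0.115%, 0.113% and 0.109%. Erythroid and platelet markers took 0.190%, 0.208% and 0.135% (0.181% and 0.0892% in the iBP libraries), conventional CD4 markers 0.0340%, 0.0330% and 0.0378%, and gamma-delta, NK and innate lymphoid markers 0.0180%, 0.0204% and 0.0188%. The CD8 markers, 2 genes, took 0.0024%, 0.0025% and 0.0031%, and stromal and endothelial markers 0.00749%, 0.00471% and 0.00596%. In stimulated against unstimulated libraries, 0 members of the B-cell (adjusted p of the list 0.734), conventional CD4 (0.452), innate lymphoid (0.448), myeloid (0.381), dendritic (0.448) and erythroid (0.693) lists passed, over all genes or adjusted over the list alone. The CD8 and stromal lists had too few members above the filter to be tested, and 0 of 13 mitochondrially encoded genes are in the table.

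The second comparison, stimulated with iBP against stimulated, asks how the stimulated state differs in the presence of iBP. H2AK119ub1 was not measured in these data, so how far iBP lowered the mark is unknown. Only Dnajb11 passed: it read 2.69 and 2.44 FPKM in stimulated and 16.1 and 14.0 in iBP libraries, a log2 difference of 2.17 ± 0.23 (SE; 95% interval 1.67 to 2.66; adjusted p = 0.00813). With iBP it was near its unstimulated level of 21.0 and 16.9 FPKM, from which it differed by −0.31 (adjusted p = 0.648). Of 10436 genes, limma called 1, and 498 had an unadjusted p under 0.05 where 521.8 would be reached by chance. Simulated comparisons with no change gave 1.3 calls on average and at least 1 call in 12 of 20 runs, so a count of 1 is not above that number. The 95% interval of a gene's difference had a median half-width of 0.57 before adjustment for the number of genes. In simulated data with these group sizes and 200 changed genes, the test recovered 53.3% of changes of 1 and 12.1% of changes of 0.5. Many changes above that half-width would thus also be missed. Where fewer genes change, the adjusted threshold is stricter, so recovery in this comparison may be lower than in those simulations. The Dnajb11 call ended without stimulated replicate 1 (adjusted p = 0.0563) or stimulated replicate 2 (0.136), without the filter on low values (0.359) and without the variance trend (0.2). Without iBP replicate 1, 5 genes passed (Eif3j2, Naca, Hba-a2, Chkb and Dnajb11), and without iBP replicate 2, 3 did (Dpm1-adnp, Rpl26 at 2.29, and Dnajb11). Of these only Dnajb11 and Rpl26 come under the rule for named genes, and the others are named because they passed.

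Genes with the next smallest unadjusted p did not pass. Hibch, a mitochondrial enzyme of valine breakdown, read 1.52 and 0.985 FPKM in stimulated and 8.12 and 7.32 in iBP libraries (log2 1.96 ± 0.32, adjusted p = 0.302). Hspa1a and Hspa1b, near-identical genes of the inducible HSP70 chaperone whose reads may be shared, stood at 0.70 (adjusted p = 0.683) and 0.72 (0.774). Snord42a, a small nucleolar RNA gene inside Rpl23a on the same strand, stood at 1.20 (0.6) and Rpl23a itself at −0.01. Rn45s, the 45S ribosomal RNA precursor, is named after its values were seen, and in poly(A) libraries its level also depends on carry-over of ribosomal RNA. It read 577 and 598 FPKM unstimulated, 735 and 585 stimulated and 877 and 1098 with iBP (0.58 ± 0.14 for iBP against stimulated, adjusted p = 0.774). On the lower side, Scand1, a zinc-finger partner gene, had a mean of 6.68 ± 0.565 FPKM in stimulated and 2.03 ± 0.0973 in iBP libraries (−1.34 ± 0.26, adjusted p = 0.6). Cd79b, a B-cell receptor component, read 336 and 340 against 222 and 244 FPKM (−0.54 ± 0.11, adjusted p = 0.6). Tusc3 stood at −0.91 and Abhd10 at −1.03. Among lineage and effector genes, Il22 stood at −0.58 (adjusted p = 0.998), Csf2 at −0.59 (0.998), Il17a at −1.20 ± 0.31 (0.959), Il17f at −0.95 (0.998) and Ifng at 1.25 (0.998). Ifng, the interferon gamma gene, read 13.1 and 3.08 FPKM without iBP and 21.2 and 13.6 with it. Foxp3 stood at 0.15 and Il2ra at −0.18, and Bcl6 and Cish at 0.00 or −0.00.

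At a preset correlation, 4 of 37 lists passed with iBP, 2 higher and 2 lower; 0 passed with an estimated correlation or with fry in 1 direction. With fry for change in either direction 5 passed: unfolded protein response (adjusted p = 0.00314), cholesterol synthesis (0.0105), p53 response (0.0252), ribosome biogenesis (0.0326) and heat shock (0.0326). Ribosome biogenesis genes were lower, with a median of −0.18 and 33 of 41 differences negative (adjusted p = 0.00651; adjusted p = 0.735 with an estimated correlation). The largest were Noc2l at −0.65 and Wdr12 at −0.63. Cholesterol synthesis genes were higher, with a median of 0.19 and 18 of 23 positive (adjusted p = 0.00651; adjusted p = 0.735 with an estimated correlation). Hmgcs1, which encodes HMG-CoA synthase, stood at 0.81 and Mvk, mevalonate kinase, at −0.71. Ribosomal protein genes were higher, with a median of 0.11 and 31 of 36 positive (adjusted p = 0.0117; adjusted p = 0.893 with an estimated correlation), among them Rpl26 at 1.54 and Rps27 at 0.64, with Rps2 at −0.48. Myeloid markers were lower, with a median of −0.20 and 10 of 13 negative (adjusted p = 0.0309; adjusted p = 0.735 with an estimated correlation), among them C1qb at −0.98 and Tyrobp at −0.77. In these 4 lists 0 members passed over all genes, and 1 rose adjusted over the list alone, Hmgcs1. Without iBP replicate 2 all 4 calls ended (ribosome biogenesis and cholesterol synthesis 0.0782, ribosomal proteins and myeloid markers 0.334). Without stimulated replicate 2, ribosome biogenesis and cholesterol synthesis had an adjusted p of 0.148, and the median of ribosomal proteins turned to −0.08 (0.596). Ribosome biogenesis also lost its call without iBP replicate 1 (0.0528), and myeloid markers without stimulated replicate 1 (0.491) and with a minimum FPKM of 5 (0.665).

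Among lists that did not pass with iBP, effector cytokines had a median of −0.25 and 14 of 20 negative (adjusted p = 0.212), with 0 members past the test over all genes and 1 lower adjusted over the list alone, Il17a. Cell cycle genes had a median of −0.14 and 38 of 52 negative (adjusted p = 0.112). The heat shock list had 0 members past the test over all genes and 2 higher adjusted over the list alone, Hspa1a and Hspa1b (list adjusted p = 0.212). With a minimum FPKM of 5 it passed (0.0432), as did resting and naive T-cell genes, higher with a median of 0.03 (0.0432; 0.151 at the usual filter). B-cell markers had 1 lower member adjusted over the list alone, Cd79b (list adjusted p = 0.995), while Cd79a and H2-Aa stood as given above. The IL-2/STAT5 list had a median of −0.02 (adjusted p = 0.868) and the Treg core list 0.00 (0.758), and 0 members of either passed.

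Genes that differed with stimulation on average over both stimulated groups kept most of that difference under iBP. They were picked by the mean of the 4 stimulated libraries against the unstimulated ones: 158 raised and 96 lowered. The errors of that contrast are independent of those of iBP against stimulated. A gene that lost its response under iBP has a smaller mean difference and is less likely to be picked. The choice thus favours genes that kept their response, and a loss in other genes could be missed. The raised genes had a median iBP difference of −0.02, with 70 higher and 88 lower (camera p = 0.856; estimated-correlation p = 0.931; fry p = 0.487). This median was within 0.03 of 0 and turned positive after rescaling to TPM (0.02), median-of-ratios scaling (0.02) or quantile normalization (0.03). These scalings also moved the median of all genes, from −0.035 to 0.002, −0.0005 and 0.005. The median of the raised set lay above that of all genes in each of them and in the main fit. It was also positive without stimulated replicate 2 (0.02) and without iBP replicate 1 (0.02), and was −0.08 without stimulated replicate 1. The lowered genes had a median of −0.08, with 23 higher and 72 lower, against −0.03 over all genes (camera p = 0.0096; estimated-correlation p = 0.116; fry p = 0.0381). Dnajb11 was the only member of either set past the test with iBP. The call of the lowered set ended without unstimulated replicate 2 (median −0.11) or stimulated replicate 1 (median −0.04). It held without unstimulated replicate 1 (median −0.19), stimulated replicate 2 (−0.10), iBP replicate 1 (−0.18) or iBP replicate 2 (−0.21). It ended with the few genes left without the filter (4) or without the variance trend (6). Leaving out a stimulated or iBP library unbalances the groups and makes the choice of response genes depend on the iBP difference, so values of both sets without such a library do not test the call. The median of the lowered set was −0.05 after rescaling to TPM, −0.04 after median-of-ratios scaling and −0.03 after quantile normalization. Averaged over each set, the raised genes stood 1.09 and 1.17 above the unstimulated mean in stimulated and 1.10 and 1.08 in iBP libraries, and the lowered genes at −0.74 and −0.84 against −0.91 and −0.91.

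**Figure D2:**
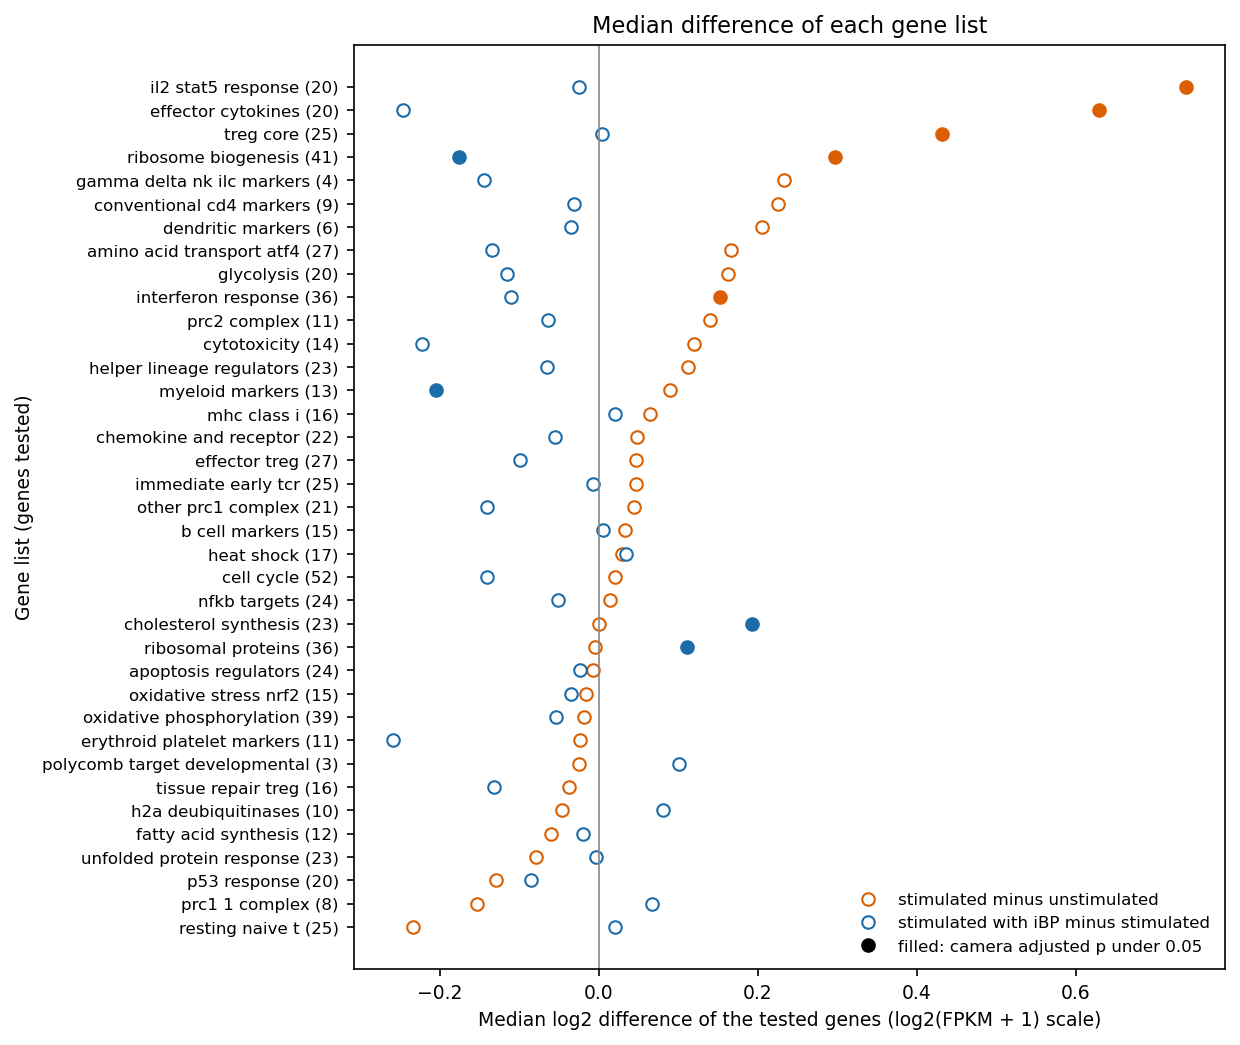
Median log2 difference of the members of 37 gene lists, stimulated minus unstimulated in orange and iBP minus stimulated in blue, filled where the camera adjusted p is under 0.05. The IL-2/STAT5 list lies at 0.74 for stimulation and at −0.02 for iBP, and ribosome biogenesis at 0.30 and −0.18.

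The last comparison, stimulated with iBP against unstimulated, gives the joint difference of stimulation and iBP. There were no unstimulated libraries with iBP. A response altered by iBP therefore cannot be separated from an effect that iBP has without stimulation. Il22 rose by 5.15 ± 0.22 (SE; adjusted p = 2.62e-07), Socs1 by 2.77 ± 0.12, Gpr83 by 2.36 ± 0.12 and Gpr146 by 2.17 ± 0.24, and Foxp3 by 1.57 ± 0.16 (adjusted p = 0.000482). Mir704, within Pdia4, rose by 2.72 (adjusted p = 0.0187). Bcl6 fell by 2.18 ± 0.17, and Scand1 differed by −2.09 ± 0.26 (adjusted p = 0.00165), from 10.6 and 13.3 FPKM to a mean of 2.03 ± 0.0973 (SD). Other named falls were Hes1, a transcriptional repressor and Notch target (−2.32 ± 0.46, adjusted p = 0.028), Lsm4, an RNA-processing gene (−1.70, 0.00627), and Micu2, a regulator of mitochondrial calcium uptake (−1.57, 0.0262). Hspa1a rose by 0.73 (adjusted p = 0.0299), Il2ra by 0.74 (0.0116) and Ctla4 by 0.51 (0.0412). In all, 183 genes passed, 107 higher and 76 lower, and 93 differed at least 2-fold. The lower ones numbered 49 after rescaling to TPM, 60 after median-of-ratios scaling and 65 after quantile normalization. Scand1, Hes1, Lsm4, Micu2, Hspa1a and Ctla4 passed here and not in stimulated against unstimulated, but their direct difference between iBP and stimulated libraries did not pass.

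Calls in this comparison ended for Hes1 without unstimulated replicate 1 (adjusted p = 0.149), unstimulated replicate 2 (0.0771), iBP replicate 1 (0.114) or iBP replicate 2 (0.157). For Ctla4 they ended without the same 4 libraries (0.167, 0.0629, 0.301 and 0.28), and for Hspa1a likewise (0.0752, 0.0921, 0.194 and 0.208). Il2ra lost its call without unstimulated replicate 2 (0.055), iBP replicate 1 (0.141) or iBP replicate 2 (0.0937), and Micu2 without unstimulated replicate 2 (0.109) or iBP replicate 2 (0.217). Lsm4 lost it without iBP replicate 2 (0.0606), and Mir704 without iBP replicate 2 (0.17) or unstimulated replicate 1 (0.0665). The number of genes past the test was 53 without iBP replicate 2, 76 without iBP replicate 1 and 95 without unstimulated replicate 1.

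With iBP against unstimulated, 4 lists rose at the preset correlation and 0 fell. The IL-2/STAT5 list had 11 rises of 20 (11 adjusted over the list alone; median 0.69, adjusted p = 5.57e-08; adjusted p = 0.194 with an estimated correlation) and the Treg core list 11 of 25 (13 adjusted over the list alone; median 0.49, adjusted p = 6.57e-07; adjusted p = 0.224 with an estimated correlation). Effector cytokines had 4 rises and 1 fall of 20 (7 and 1 adjusted over the list alone; median 0.62, adjusted p = 1.74e-06; adjusted p = 0.194 with an estimated correlation). Ribosome biogenesis had a median of 0.14 with 0 members past the test, over all genes or adjusted over the list alone (adjusted p = 0.0347; adjusted p = 0.699 with an estimated correlation). That call ended without unstimulated replicate 1 (0.112), unstimulated replicate 2 (0.0667), iBP replicate 1 (0.0885) or iBP replicate 2 (0.125). Ribosomal protein genes passed as a list only without unstimulated replicate 1 (higher, 0.0459). Cholesterol synthesis (median 0.21, adjusted p = 0.0532) passed with a minimum FPKM of 5 (0.0204) and with quantile normalization (0.0486).

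The responses with and without iBP shared most of their genes: 84 genes were higher and 28 lower in both, and 0 moved in opposite directions. Independent lists would share 1.04 and 0.248, and simulated data with no effect but the same shared controls shared 0.29 on average and at most 2. With no effect few genes pass in either comparison. The simulated number thus does not measure how much sharing the controls create among genes that respond. Both comparisons use the same pair of unstimulated libraries, which is too few to split, so part of the excess may come from those controls. Across genes, the covariance of the changes with and without iBP was 0.112, against 0.0428 ± 0.00124 (SD) in 100 simulations with no effect. The covariance of the stimulation change with the iBP change was −0.048, against −0.0425 ± 0.00133 in simulations in which the shared stimulated libraries alone give a negative value. The difference from the simulated value was thus 0.069 for the former and −0.00548 for the latter. The simulations drew each gene independently from its moderated variance. Their SD therefore leaves out correlation between genes, and their spread may differ from that of the data. No conclusion is drawn from the difference of −0.00548.

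Polycomb genes were examined because iBP is described as inhibiting the mark that PRC1 places and the study concerns the variant complex PRC1.1. Kdm2b, the CpG-island binding subunit of PRC1.1, read 56.5 and 56.2 FPKM unstimulated, 43.5 and 48.7 stimulated, and 41.3 and 39.3 with iBP. Its differences were −0.29 ± 0.14 with stimulation (adjusted p = 0.502), −0.19 with iBP against stimulated (0.998) and −0.47 with iBP against unstimulated (0.148), where it was lower adjusted over the list alone. None of the 8 tested PRC1.1 genes passed over all genes in any of the 3 comparisons (list adjusted p = 0.365, 0.72 and 0.527). With stimulation, Bcor stood at −0.39, Rnf2, an E3 ligase subunit, at −0.24, and Pcgf1 at −0.06. Of genes in other PRC1 complexes 0 of 21 passed with stimulation, over all genes or adjusted over the list alone (list adjusted p = 0.779), among them Bmi1 at 0.22. The sign turned for Pcgf1 without unstimulated replicate 2 (0.05) or stimulated replicate 2 (0.06) and for Bmi1 without unstimulated replicate 1 (−0.28). With iBP against stimulated Rnf2 stood at 0.15, and at −0.01 without stimulated replicate 2. Ring1 was below the filter, at 0.384 and 0.438, 0.312 and 0.24, and 0.147 and 0 FPKM. Ezh2, the methyltransferase of PRC2, read 7.01 and 5.76, 13.5 and 17.8, and 14.1 and 15.6 FPKM.

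Ezh2 was the 1 member of 11 PRC2 genes that rose with stimulation, by 1.17 ± 0.22 (adjusted p = 0.0263; list adjusted p = 0.222; 1 rise adjusted over the list alone). Its call ended without stimulated replicate 1 (0.0587), stimulated replicate 2 (0.276), unstimulated replicate 1 (0.0512), unstimulated replicate 2 (0.0845) or iBP replicate 2 (0.0529). With iBP it stood at −0.06 against stimulated. Of the H2A deubiquitinase genes, 0 of 10 passed with stimulation (list adjusted p = 0.734) or with iBP against stimulated (0.253). Of 98 developmental Polycomb target genes 3 were above the filter and 0 passed (0.779 with stimulation, 0.351 with iBP against stimulated, 0.314 with iBP against unstimulated). All 3 were positive with iBP against either group, with a median of 0.32 against unstimulated (fry adjusted p = 0.013; adjusted p = 0.699 with an estimated correlation in camera) and 0.10 against stimulated (fry adjusted p = 0.233). Cdkn2a, a target silenced by Polycomb in many cell types, was listed at 0 in all 6 libraries, and Cdkn1a, a cell cycle inhibitor gene, stood at −0.17 with stimulation, and at 0.07 without unstimulated replicate 1.

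**Figure D3:**
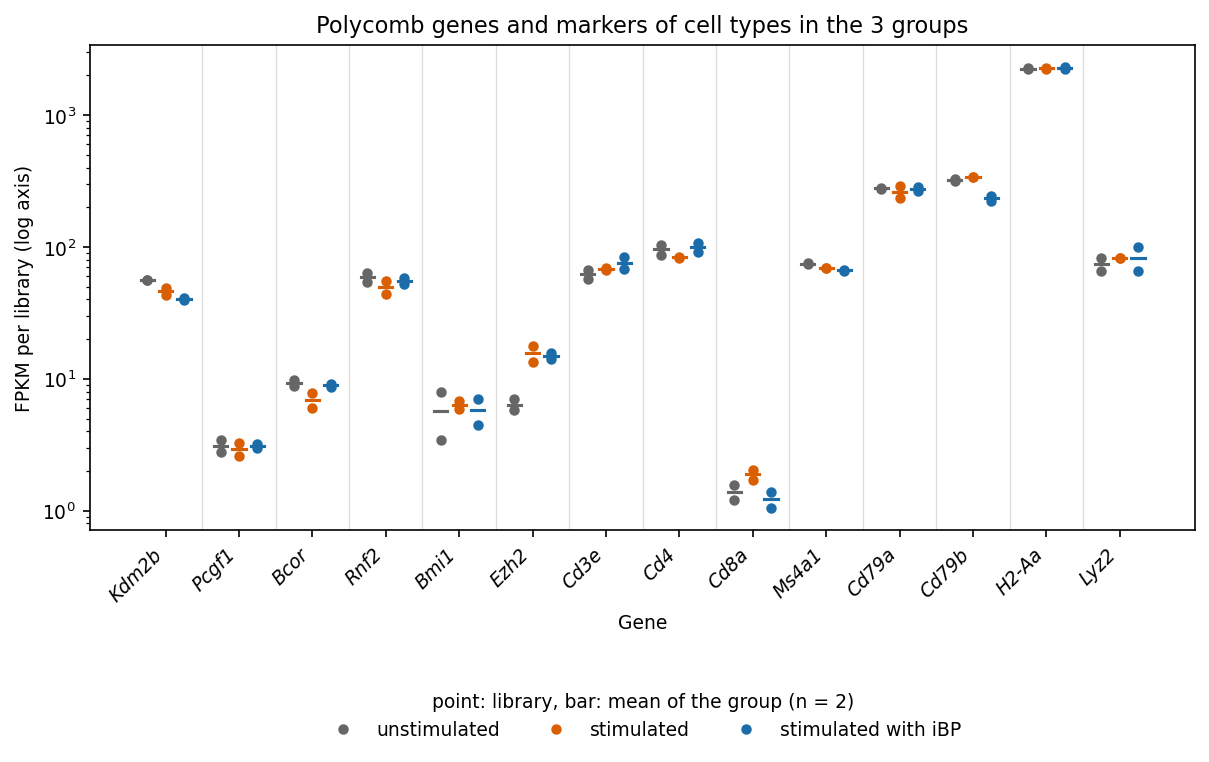
FPKM on a log axis of Polycomb genes and of T-cell, B-cell and myeloid markers in each library, with points for libraries and bars for group means (n = 2). Kdm2b lies between 39.3 and 56.5 in all libraries, and the B-cell gene Cd79b at 222 and 244 with iBP against 314 to 340 in the other 4.

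In the GRCm38 (mm10) assembly Il22 lies on chromosome 10 at 118204942 to 118210047, Socs1 on chromosome 16 at 10782240 to 10785536, Gpr83 on chromosome 9 at 14860210 to 14870789 and Foxp3 on chromosome X at 7573644 to 7595245. Csf2 lies on chromosome 11 at 54247271 to 54249667 and Il17a on chromosome 1 at 20730905 to 20734496. Bcl6 lies on chromosome 16 at 23965052 to 23988852 and Kdm2b on chromosome 5 at 122870665 to 122989823. Dnajb11 lies on chromosome 16 at 22857845 to 22879634, next to Tbccd1 at 22813214 to 22857669 on the opposite strand. Mir704 lies on chromosome 6 at 47803576 to 47803652 within Pdia4, and Mir6974 on chromosome 17 at 35204475 to 35204557 within Lta at 35203165 to 35205351.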

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

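Leaving out microRNA and small nucleolar RNA genes was chosen after seeing the data and gave 150, 1 and 198 genes past the test in stimulated against unstimulated, iBP against stimulated and iBP against unstimulated, where the full set gave 135, 1 and 183. Without the filter on low values the counts were 12, 0 and 11, and without the variance trend 12, 0 and 9, so the length of the gene lists rests on both choices. All 12 genes left in the first comparison without the filter were among the 135. A replicate block, with the replicate number as a term, gave 79, 1 and 109, of which 76, 1 and 109 were among the original genes. It leaves fewer degrees of freedom, and deviations of equally numbered replicates were not correlated across genes between groups (pairing correlations of −0.0462, −0.0185 and −0.0118). With only 2 groups in the fit, stimulated against unstimulated gave 79 genes. A 2-fold minimum gave 72 and 93 genes in the first and last comparison, and an adjusted p under 0.1 gave 243 and 302. Without 1 library the counts ranged from 54 to 141, from 0 to 5 and from 53 to 190.

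With an estimated correlation 0 lists passed in each comparison, and fry passed 0 lists for iBP against stimulated, where leaving out 1 library gave 0 to 4. The median iBP difference of the raised response genes was 0.0224 after rescaling to TPM, 0.0243 after median-of-ratios scaling and 0.0348 after quantile normalization. Under these scalings the median of all genes moved as well, from −0.0347 to 0.00209, −0.000534 and 0.00527. The change of sign is thus not a change relative to the other genes. The median of the raised genes ranged from −0.0832 to 0.0226 without 1 library. The lowered response genes had medians of −0.000567 without the filter (4 genes) and −0.000567 without the trend (6 genes), and −0.207 to −0.0390 without 1 library. Without a stimulated or iBP library the choice of these genes is no longer independent of the iBP difference. The covariance of the stimulation and iBP changes was −0.134 with a pseudocount of 0.1, −0.0418 without the filter, −0.0309 with a minimum FPKM of 5, −0.0943 after TPM rescaling, and −0.109 to −0.0462 without 1 library. Genes that did not pass and changed sign without 1 library were, with stimulation, Pcgf1 (−0.182 to 0.0561), Bmi1 (−0.28 to 0.72) and Cdkn1a (−0.400 to 0.0677), and with iBP against stimulated Rnf2 (−0.0059 to 0.31). Of 66 gene results past the test in the text, 33 stayed past it without any 1 library and 11 under all 17 alternatives tried for them. The cause of these differences was not tested, and what read depth limits is unknown.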

Other observations

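Stimulation also moved genes of survival, NF-kappaB signalling and Treg function whose lists as a whole did not pass at the preset correlation. Among apoptosis regulators 3 of 24 genes rose and 0 fell (5 rose adjusted over the list alone; list adjusted p = 0.366, or 0.0206 with a minimum FPKM of 5; fry adjusted p = 0.0286; median −0.01 and mean 0.14): Bcl2, Fas and Mcl1, the last an anti-apoptotic gene at 0.92 (adjusted p = 0.0192). Mcl1 lost its call without stimulated replicate 1 (0.0794), stimulated replicate 2 (0.175) or unstimulated replicate 1 (0.106). Among NF-kappaB targets 4 of 24 genes rose and 1 fell (4 and 2 adjusted over the list alone; list adjusted p = 0.366). The rises included Tnfaip8 (1.26), Nfkbiz (1.20, an atypical I-kappaB that promotes Il17a transcription) and Map3k8 (1.03), and the fall was Tnfaip3 (−0.66), the negative regulator A20. Without stimulated replicate 2, Map3k8 (0.111) and Tnfaip3 (0.0887) lost their calls, as did Tnfaip3 without unstimulated replicate 2 (0.0516).

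Effector Treg genes had 4 rises and 2 falls of 27 (7 and 3 adjusted over the list alone; list adjusted p = 0.366, fry adjusted p = 0.00482), with Icos (1.01) and Tnfrsf9 (0.92), both costimulatory receptor genes, higher and the chemokine receptor gene Ccr8 lower (−0.56). Tissue-repair Treg genes had 2 rises and 1 fall of 16 (2 and 3 adjusted over the list alone; 0.693): Itgb8 (1.06), which encodes an integrin chain that activates TGF-beta, Ptger4 (0.87) and Penk (−0.72), the proenkephalin gene. The largest difference in that list, Tff1 at −1.69, did not pass (adjusted p = 0.0511) but did in 2 alternatives (lowest adjusted p 0.0355). Chemokine and receptor genes had 0 rises and 2 falls of 22 (1 and 3 adjusted over the list alone; 0.861), Ccr7 and Ccr8, while Ccr4 stood at 1.26 (adjusted p = 0.0701). Without stimulated replicate 2 the adjusted p was 0.053 for Ccr8, 0.258 for Itgb8, 0.148 for Ptger4 and 0.0652 for Penk. Without stimulated replicate 1 it was 0.127 for Ccr8, 0.119 for Ptger4 and 0.0647 for Penk. Without unstimulated replicate 1 it was 0.137 for Ccr8, 0.11 for Ptger4 and 0.0797 for Penk. Itgb8 also lost its call without unstimulated replicate 2 (0.0888), and Ccr8 without iBP replicate 1 (0.0748) or 2 (0.0766). A list of pancreatic acinar genes, chosen after their values were seen, had median FPKM of 1.81 and 2.50 in unstimulated, 1.86 and 5.64 in stimulated and 1.98 and 1.84 in iBP libraries, so that it stood out in stimulated replicate 2 and not in replicate 1. Because the list was chosen on these values, no test of it is given.

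The tests on the share of T cells and of Treg, on the unfolded protein response and on the reads of Tbccd1 were chosen after the results were seen. The IL-2/STAT5 list rose with stimulation by a median of 0.74 at the preset correlation (adjusted p = 0.152 with an estimated correlation). The 17 general T-cell genes did not rise alongside the IL-2/STAT5 list and had a median of −0.15, with 5 above 0 and 12 below. The upper 95% bound was 0.0261, from resampling the genes, so it leaves out the spread between libraries. These genes took 0.532% and 0.494% of summed FPKM in unstimulated libraries, and 0.499% and 0.487% in stimulated ones. Members of the general T-cell list moved apart, with 2 higher and 1 lower adjusted over the list alone, and stimulation may itself change them. They argue against a higher share of T cells only if it does not, which was not tested. A higher share of Treg as the whole cause is argued against, since Treg-restricted genes moved apart. Nrp1, the lowest of 7, minus Foxp3 was −1.72 ± 0.24 (SE). Ikzf2 stood at −0.19, Izumo1r at 0.18, Ikzf4 at 0.61, Lrrc32 at 1.16 and Gpr83 at 2.32. These 7 genes were higher as a list (median 0.61, camera adjusted p = 0.000529, or 0.104 with an estimated correlation), so a higher share may still account for part of the rise. The list was made after the results were seen and its p was adjusted only over lists made then. These p-values are therefore descriptive. Signalling through the IL-2 receptor would lower Il7r and Il6st and raise Il12rb1 and Il12rb2: all 4 differed in that direction (−0.37, −0.26, 0.50 and 0.66) and 0 had an unadjusted p under 0.05, so this stays open.

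Dnajb11 was lower after stimulation and not with iBP. Induction of the unfolded protein response by iBP to the extent seen for Dnajb11 is argued against. The 22 other members of that list had a median of −0.01 with an upper 95% bound of 0.126, while the lower bound for Dnajb11 was 1.67. The bound of the list comes from resampling its genes and leaves out the spread between libraries. Dnajb11 was picked for its difference, so a smaller induction of the list stays open. Failures of quantification that strike all genes at an equal rate, independently in both stimulated libraries, are argued against. They would give 0.0026 such genes among 3461 of like level, and 1 was seen, Dnajb11 itself. That rate does not cover a gene more prone to fail than others, so repeated failure of Dnajb11 stays open. Whether reads moved between Dnajb11 and its neighbour Tbccd1 stays open. Summed over both genes, FPKM times length in stimulated libraries was 57.4% of that with iBP, against 17.1% for Dnajb11 alone. Per library the sum was 35.0 and 41.4 in stimulated, 70.2 and 62.9 with iBP and 73.7 and 75.2 in unstimulated. Adding a neighbour that does not change would also raise the percentage. The part of the sum that came from Tbccd1 was, however, larger in both stimulated libraries than in any other library. A move of some reads is thus possible, but a change of Tbccd1 itself would look alike. A change of transcript model or of Dnajb11 transcription itself stays open, and H2AK119ub1 at this gene was not measured here.

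Ribosome biogenesis genes were higher after stimulation (median 0.30) and lower with iBP than without (−0.18) at the preset correlation, and passed neither with an estimated correlation (adjusted p = 0.262 and 0.735). Because both comparisons share the stimulated libraries, a chance deviation of those libraries could give both. The list was also higher with iBP than in unstimulated libraries, a comparison that leaves them out (adjusted p = 0.0347), but with an estimated correlation its adjusted p was 0.699 (p of 0.143 before adjustment) and the call ended without any 1 of those 4 libraries, so this stays open. A single deviating stimulated library is argued against, since the iBP median was −0.192 without replicate 1 and −0.143 without replicate 2. An effect of H2AK119ub1 inhibition on these genes is a hypothesis that these data leave open.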
